A study of Mus musculus with 16 samples.

How the data were processed

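RNA of T cells from OT-I mice was measured by sequencing in 16 libraries, 4 from each combination of tissue (lymph node or visceral adipose tissue) and diet (standard chow or high-fat diet, 8 weeks). The deposited table holds raw counts per gene, as whole numbers with no normalisation, in 54456 gene rows and 16 sample columns, and all columns were used. Per the submitters' processing notes, kallisto 0.42.4 and DESeq2 were used with the build GRCh38. That is a human build, while the gene names of the table are those of mouse, and the notes do not say how kallisto's estimates became whole counts per gene. No coordinates are given here because the build behind the table is not known. A part of the labels describes another cell type and more than 1 library kit and sequencer are named, so the library chemistry and read length are not known with certainty. The labels give no batch, date or pairing of the libraries.

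Of the gene rows, 33950 had a count in at least 1 library, 1399 carried an Ensembl identifier in place of a symbol, and 50636 matched a table of gene names. Totals were 40212388 to 65957407 counts per library, and 3 counts in a library are 0.04371 to 0.08035 CPM after normalisation. Counts came from PCR-amplified cDNA, so reads are not independent molecules. Genes that passed edgeR's filterByExpr with the 4 groups (15675) were tested. Levels are CPM with TMM-normalised library sizes.

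Genes were tested with edgeR 4.0.16 (robust dispersions, common dispersion 1.52, quasi-likelihood F-test, all 4 groups in the fit) in R 4.3.3, with Benjamini-Hochberg adjustment over the genes tested and a threshold of 0.05. The comparisons were HFD VAT against HFD LN, lean VAT against lean LN, HFD against lean VAT, HFD against lean LN, and the difference between the diet effects of VAT and LN. Groups, comparisons, the rule for named genes, 30 gene lists and the alternatives were chosen before the data were examined, except where stated. The rule takes 16 panel genes, up to 6 rises and 6 falls per comparison that passed the test with no overlap between libraries (a condition not applied to the difference between diet effects) and at least 5 CPM in the higher group, and up to 2 members per list and direction that passed, and leaves out receptor and immunoglobulin segments, mitochondrial genes and unnamed gene models from the rises and falls. It named 96 genes, and some of them are not reported here.

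The lists hold 714 distinct genes, of which 705 are in the table and 33 are in more than 1 list. Folr4, Tcrg-C1, Tcrg-C2, Tcrg-C4, Tcrg-V6, Cd163l1, Aldoa, Atp5o and Ddit3 are not in the table under these names and were not analysed here. The 25 lists with at least 5 members tested were compared with all other genes by camera of limma 3.58.1 on voom values, with a preset correlation of 0.01 between genes and, as an alternative, an estimated correlation. fry of the same package gave a second test, whose p asks whether the genes of a list move on balance in the same direction and does not compare the list with other genes. With the estimated correlation 10 of 16 list calls held for tissue on HFD, 12 of 16 for tissue in lean animals, 2 of 3 for diet in VAT and 0 of 1 for diet in LN. Library measures were compared by exact two-sided permutation tests, whose smallest possible p with 4 against 4 is 0.0286, adjusted over 60 tests. Ratios against a group with 1 to 3 counts carry 95% counting intervals, those against 0 counts are lower bounds against 3 counts in each library of the group, and shares carry Wilson 95% intervals in the tables.

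Alternatives were RLE and upper quartile normalisation, no filter, a filter of 5 CPM in 4 libraries, DESeq2 1.42.0, limma voom with quality weights, only the groups compared, replicate numbers as blocks, a macrophage covariate and leaving out each library. After seeing the data, fits without the 3 VAT libraries with the largest missing share, with genes of at least 50 CPM on average, and with voom weights held at their 99th percentile were added. In all, 167 settings were run. Comparisons were repeated on all 35 splits of the libraries of 2 groups, or on 100 drawn splits for the difference between diet effects, with the list tests at held weights. The pipeline was tested on simulated data with the dispersions of these libraries: edgeR called 0 unchanged genes and found 19.4% of 62 genes changed 8-fold between HFD and lean VAT, 18.2% of 66 between tissues on HFD, 14.3% of 63 between tissues in lean animals and 6.15% of 65 for the difference between diet effects. Python 3.11.15 with NumPy 2.4.6, SciPy 1.17.1, pandas 2.3.3 and Matplotlib 3.10.9 read the table, ran the exact tests and drew the plots.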

Results

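RNA was sequenced from T cells of OT-I mice, whose transgenic receptor recognises an ovalbumin peptide on MHC class I and which therefore make mostly CD8 T cells. The cells came from lymph node (LN) or from visceral adipose tissue (VAT), and were sorted as T cells. The labels call them freshly isolated in one place and cultured overnight before the sort in another, so effects of culture on activation and stress genes are not known. Every library also carries the term Neg-OVA, which the labels do not explain. The mice had been kept for 8 weeks on standard chow (lean) or on a high-fat diet (HFD) with 60% of its calories from fat. There were 4 groups of 4 libraries, and the series has no other samples. Levels are TMM-normalised CPM (counts scaled to a common library total), given as mean ± SD over the 4 libraries of a group. Adjusted p-values of genes come from edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment over the 15675 genes tested, and those of gene lists come from limma's camera test adjusted over the 25 lists tested.

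Total counts per library were 42444506 to 54019116 in HFD LN, 40212388 to 51726642 in HFD VAT, 49323455 to 65957407 in lean LN and 42993946 to 63617074 in lean VAT. In single libraries 3 counts correspond to 0.04371 to 0.08035 normalised CPM, and such floors and all counting intervals below cover counting error only. The p-values measure the spread between libraries, which may be partly technical. The receptor segments of the transgene were present throughout. The Trbv12 family took 99.6% to 99.999% of the counts on beta chain variable segments in the 16 libraries, and the Trav14 family took 52.2% to 89.1% of those on alpha chain segments. Xist, transcribed from the inactive X chromosome of females, reached at most 0.0249 CPM, and the Y-linked gene Eif2s3y lay between 146 and 435 CPM. No 2 libraries of a group were alike within sampling noise: the chi-square over its degrees of freedom was 320 to 1180 in the 24 replicate pairs. The first principal component took 24.3% of the variance and put every LN library on one side and every VAT library on the other.

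Libraries also differed in how many genes they held. HFD VAT libraries had a count for 16935 ± 424 genes, lean VAT libraries for 18922 ± 1219, HFD LN libraries for 18895 ± 538 and lean LN libraries for 19492 ± 510. Among genes with a median of at least 10 CPM in the other libraries of a group, 11.2% were at 3 counts or fewer in replicate 1 of HFD VAT, 11.3% in replicate 3 of HFD VAT and 13.1% in replicate 1 of lean VAT. In the other 13 libraries that share was 0.797% to 5.31%.

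**Figure D1:**
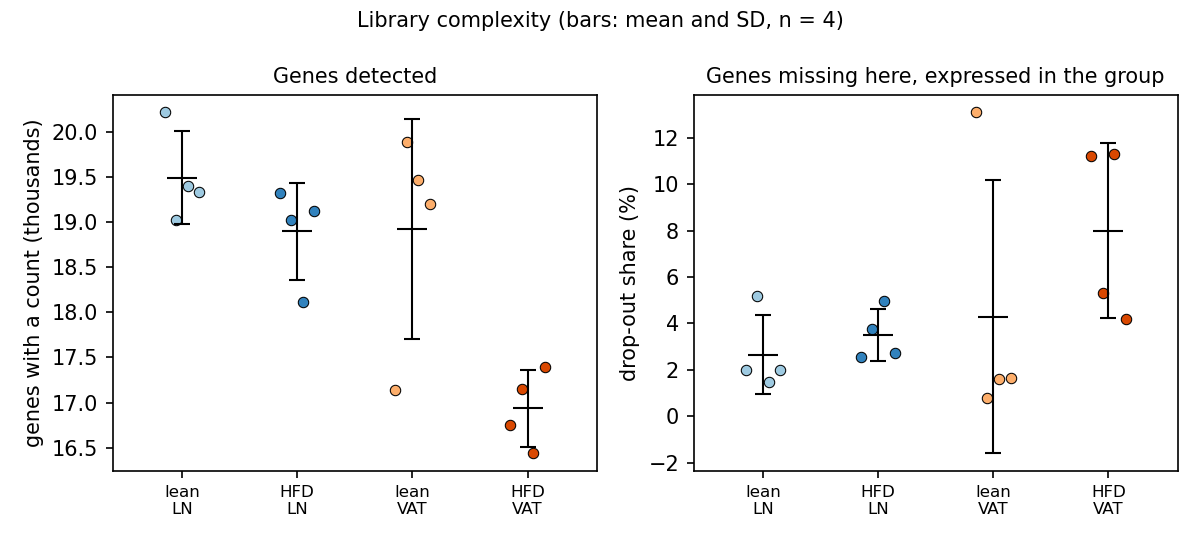
Genes with a count (left) and the share of genes expressed in the rest of a group that were at 3 counts or fewer in a library (right, percent), with 1 point per library and bars for the mean and SD of each group (n = 4). The HFD VAT libraries held 16436 to 17395 genes, and 3 VAT libraries had a missing share above 11%.

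The comparison of VAT with LN on HFD asks how OT-I cells of fat differ from those of lymph node in animals on that diet. The cytotoxic, interferon-stimulated and tissue residency lists were called as higher in VAT, each with a part of its members. Gzmb, which encodes the killer protease granzyme B, was 10450 ± 3730 CPM in VAT against 0.0134 ± 0.0166 CPM in LN. Irf7, a transcription factor of the interferon response, was 48.2-fold higher (3931 ± 275 against 81.5 ± 36.0 CPM), and Cd69, an early activation and retention marker, was 10.3-fold higher (1115 ± 67.0 against 108 ± 29.5 CPM). LN cells instead held the lymph node homing receptor Ccr7, which was 3.83-fold lower in VAT. Of the 15675 genes, 420 rose and 294 fell in VAT.

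The killer gene list, with 24 measured members, had 9 that rose and none that fell (17 rose when adjusted over the list alone; camera adjusted p = 2.01e-13). Besides Gzmb, whose 3 counts in the LN group give a VAT to LN ratio of 704000 (95% counting interval 241000 to 3410000), it included Klrk1, the activating receptor NKG2D. Klrk1 was 15.4-fold higher in VAT, at 1788 ± 194 against 116 ± 52.7 CPM. Id2, a regulator of effector T cell fate, was 11.4-fold higher (adjusted p = 8.63e-07). The chemokine ligand Ccl5 was 2.43-fold higher, with 1800 ± 340 CPM in VAT. Gzmk, which encodes granzyme K, had 139 ± 22.2 CPM in VAT against 4.98 ± 5.76 in LN and did not pass (adjusted p = 0.240).

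All 38 members of the interferon-stimulated list were measured, all 38 were higher in VAT, 29 rose over all genes tested and 37 when adjusted over the list alone (camera adjusted p = 6.85e-35; median log2 fold change 4.75). Mx2, an antiviral GTPase, had 155 ± 21.7 CPM in VAT and no count in LN, which makes it at least 2580-fold higher against 3 counts in each LN library, the floor used for every such bound. Among the 6 largest rises were also Cxcl10, a chemokine that draws CXCR3-bearing cells (2225 ± 230 CPM against no count, at least 37100-fold), and Ube2l6, the conjugating enzyme for ISG15 (169 ± 95 CPM against no count, at least 2810-fold). Ttc39c, another of them, had 262 ± 69.1 CPM in VAT and 1 count in LN (ratio 53000, 95% counting interval 9500 to 2090000).

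The residency list had 6 members that rose and none that fell among 23 measured (8 and 1 over the list alone; camera adjusted p = 9.53e-06). It holds Cd69 and the exonuclease gene Isg20, which was 61.9-fold higher and is also interferon-inducible. Itgae, which encodes the CD103 integrin of many resident T cells, went the other way: it had 14.7 ± 16 CPM in VAT and 317 ± 102 CPM in LN, with an adjusted p of 0.0559. The chemokine receptor Cxcr6 was 4.17-fold and Cxcr3 4.12-fold higher in VAT, while the receptors and integrins list as a whole had 2 members that rose and 5 that fell among 25 (adjusted p = 0.861). The receptor-induced early response list had 13 of 29 members that rose and none that fell (15 over the list alone; adjusted p = 2.83e-11). Tnfaip3, which restrains NF-kB signalling, was 17-fold higher in it. The checkpoint list had 4 of 18 that rose (7 over the list alone; adjusted p = 4.98e-08). Tigit, an inhibitory receptor, had 72.8 ± 57.3 CPM in VAT and 2 counts in LN (ratio 7350, 95% counting interval 2030 to 60700), and Tnfrsf18, the costimulatory receptor GITR, was 4.24-fold higher. Pdcd1, which encodes PD-1, had 165 ± 70.7 CPM in VAT against 0.297 ± 0.595 in LN and an adjusted p of 0.0679. The cytokine and chemokine list had 2 of 17 that rose (8 over the list alone; adjusted p = 1.75e-08), Ccl5 and the T cell growth factor Il2 (14.6 ± 4.43 against 1.68 ± 0.668 CPM). Ifng had 205 ± 68.7 CPM in VAT and 2.22 ± 2.83 in LN (adjusted p = 0.140), and Tnf had 105 ± 66.9 against 2.27 ± 4.52 (adjusted p = 0.250).

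The naive and central memory list was called as lower in VAT, with 11 of 22 members that fell and 3 that rose (15 and 4 over the list alone; adjusted p = 1.31e-05). Klf2, which drives the genes of lymph node recirculation, was 4.80-fold lower, at 199 ± 31.0 against 954 ± 160 CPM. Ly6c2, a marker that memory and effector cells also carry, rose 7.55-fold, and reads of its close copy Ly6c1 may not be separable from its own. The receptor complex list had no joint direction (1 rose and 2 fell of 20; 4 and 2 over the list alone; adjusted p = 0.758). Within it Cd8a was 3.12-fold higher in VAT (2077 ± 215 against 665 ± 112 CPM) while Cd8b1, the partner chain of the CD8 coreceptor, was 1.69-fold lower (1228 ± 120 against 2072 ± 133 CPM). Lat, an adaptor of receptor signalling, was 2.27-fold lower, and Cd3e did not pass (340 ± 95.3 against 385 ± 25.5 CPM). Cd44, which marks antigen-experienced cells, did not pass either (98.1 ± 34.5 against 24.1 ± 24.2 CPM). Cd4 and Il17a of the fixed panel did not pass the filter on low counts.

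Apoptosis and p53 genes were called as higher, with 4 of 23 that rose and 1 that fell (4 and 1 over the list alone; adjusted p = 0.00126). Gadd45g, a stress-induced gene, was 20.9-fold and the survival gene Bcl2a1d, one of several near-identical copies, 7.70-fold higher, and the death gene Bbc3 was 11.9-fold lower. The heat shock list (3 of 17 rose; adjusted p = 0.000213), the unfolded protein response list (4 rose and 1 fell of 25; 0.000382), the oxidative phosphorylation list (1 of 52 rose; 0.000166) and the glycolysis and hypoxia list (1 rose and 1 fell of 26; 0.0481) were called as higher, and the mitochondrially encoded list (1 of 13 fell; 0.000281) as lower. With an estimated correlation their adjusted p was 0.0688 for heat shock, 0.0740 for the unfolded protein response and 0.262 for the other 3. Adjusted over each list alone, 5 heat shock genes rose, 2 glycolysis genes rose and 1 fell, and the counts of the other 3 lists stayed as given. Hspa8, a constitutive chaperone, was 2.77-fold higher, and the endoplasmic reticulum chaperone Hspa5 was 5.43-fold higher. Gapdh was 2.41-fold and Cycs, which encodes cytochrome c, 4.17-fold higher, and mt-Cytb was 2.69-fold lower. The fatty acid list had 2 that rose and 1 that fell of 33 (adjusted p = 0.861), among them Dgat1, the last enzyme of triglyceride synthesis, 15.3-fold higher at 1006 ± 155 CPM. The cholesterol list (1 fell of 28; adjusted p = 0.187), the cell cycle list (1 rose of 37; 0.419) and the type 17 list (2 rose and 1 fell of 13; 0.823) were not called.

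Markers of other cell types differed between the tissues beside all of these groups. Every measured B and plasma cell gene was lower in VAT, and 11 of 20 fell (17 over the list alone; adjusted p = 2.87e-11). Ighm, the IgM heavy chain gene, was 5.90-fold lower (259 ± 103 against 1527 ± 245 CPM). The list's fitted median log2 fold change was -10.47, or -9.43 with genes at 0 in a group set to their bound. Of the 6 largest falls, Fcmr, an IgM receptor of B cells, had 62.0 ± 69.1 CPM in LN and no count in VAT (at least 873-fold lower), and the calcium channel gene Cacna2d4 had 87.9 ± 40.4 CPM in LN and no count in VAT (at least 1240-fold lower). The macrophage list had 2 that rose and 2 that fell of 8 (adjusted p = 0.0781): Lgals3 (27.7-fold) and Plac8 (11.2-fold), which T cells also express, rose, and Apoe fell to 1 count. The dendritic cell list had 4 of 14 that fell (adjusted p = 0.0949), with Cd74, the MHC class II chaperone that B cells share, 10.9-fold lower. Natural killer and innate lymphoid genes were higher (1 of 10 rose, 6 over the list alone; adjusted p = 8.57e-09), and Klre1, a lectin-like receptor also found on effector CD8 cells, had 463 ± 82.7 CPM against 5.86 ± 5.45 (adjusted p = 0.0180; 0.0615 without replicate 3 of HFD LN). The CD4 and regulatory T cell list was called as higher (1 rose and 1 fell of 8; adjusted p = 0.0209, and 0.0544 with an estimated correlation), although Cd40lg, the helper ligand CD40L, had 27.7 ± 8.37 CPM in LN and no count in VAT. The gamma delta list was not called (adjusted p = 0.951). The neutrophil, adipocyte, fibroblast, endothelial and erythroid lists had 2 to 4 members above the filter, too few for the list test. In these only Gsn, of the fibroblast list, was called, lower in VAT (0.0874 ± 0.175 against 35.5 ± 35.4 CPM), and its call was lost without replicates 1, 3 or 4 of HFD LN or 1, 2 or 3 of HFD VAT (adjusted p up to 0.0927), without a filter (0.0744), without the 3 VAT libraries of largest missing share (0.184), with only these groups in the fit (0.225) and with voom (0.285).

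Of the 714 genes called, 671 had no overlap between the libraries of the groups, and over all genes that share was 15.2% where chance gives 2.86%. In 178 of the 714 the lower group had 3 counts or fewer. The count was 441 without a filter on low counts, 264 with replicate numbers as blocks and 2578 with DESeq2, Gzmb and Cd74 lost their call with voom (adjusted p = 0.992 and 0.491), and the glycolysis list lost its call without replicates 1, 3 or 4 of HFD LN or replicates 2, 3 or 4 of HFD VAT (adjusted p up to 0.0980). With blocks Cxcl10, Mx2, Ube2l6, Ttc39c, Klre1, Il2, Hspa5, mt-Cytb, Fcmr and Cd40lg lost their call (0.0592 to 0.216), as did Il2 without a filter (0.116) and Mx2 and Klre1 without the 3 VAT libraries of largest missing share (0.0506 and 0.0617). Gzmk, Ifng, Itgae, Pdcd1 and Tnf, which edgeR did not call, passed with voom (0.00295 to 0.0183), Itgae and Pdcd1 passed with DESeq2 and with the stricter filter, Itgae passed without replicate 1 of HFD VAT (0.0165), Pdcd1 without replicate 3 of HFD LN (0.0404), and Tnf without replicate 4 of HFD LN (0.0361).

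**Figure D2:**
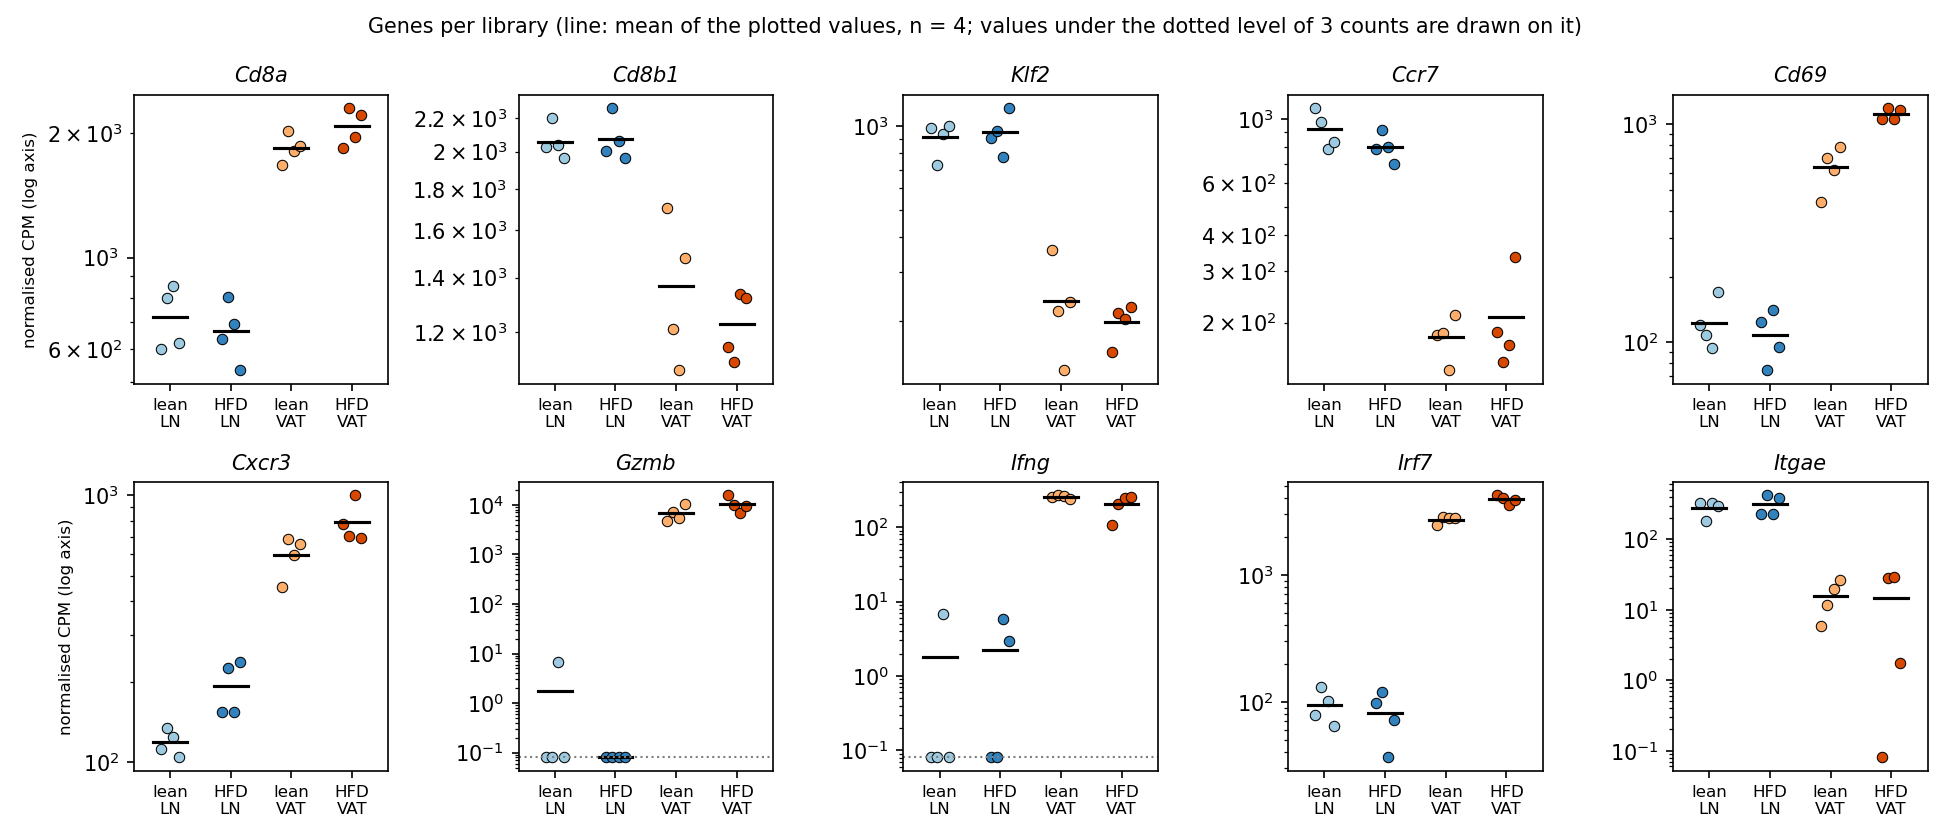
Normalised CPM of 10 genes on a log axis, with 1 point per library, the 4 groups along the horizontal axis and a line at the mean of each group (n = 4). Gzmb and Ifng reach at most 6.73 and 6.87 CPM in LN libraries and at least 4742 and 107 CPM in VAT libraries, while Klf2, Ccr7 and Itgae are lower in every VAT library than in any LN library.

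The comparison of VAT with LN on standard chow asks the same of lean animals. Lean VAT cells showed the same kinds of genes: Gzmb at 6896 ± 2470 CPM against 1.68 ± 3.37, Irf7 29.0-fold higher (2722 ± 169 against 93.7 ± 28.8 CPM), Cd69 5.17-fold higher (636 ± 147 against 123 ± 32.8 CPM) and Ccr7 5.15-fold lower (179 ± 31.1 against 920 ± 136 CPM). Of the 15675 genes, 332 rose and 144 fell in VAT. A total of 270 genes rose in both diets, where 8.9 are expected of independent lists, and 100 fell in both, where 2.7 are expected. No gene called in both went opposite ways. Across genes, which are not independent replicates, the tissue differences of the 2 diets had a Pearson correlation of 0.477 and a Spearman correlation of 0.458.

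In the lean animals the killer list had 10 of 24 members that rose (14 over the list alone; camera adjusted p = 3.44e-13). Klrc1, the receptor NKG2A, was 14.9-fold and Id2 11.6-fold higher, and Ccl5 was 4.82-fold higher at 2061 ± 666 CPM. Gzmc, another granzyme gene, was among the 6 largest rises with 57.4 ± 27.5 CPM in VAT and no count in LN (at least 1090-fold). Gzmb in LN rested on replicate 3, which held all of the 348 counts of that group. Interferon-stimulated genes rose in 26 of 38 members (37 over the list alone; adjusted p = 1.32e-31; median log2 fold change 4.28), and outside the list Ube2l6 had 132 ± 79.3 CPM against no count. The residency list had 7 of 23 that rose (12 over the list alone and 1 that fell; adjusted p = 2.14e-10). P2rx7, a receptor for extracellular ATP, had 175 ± 60.3 CPM in VAT and 1 count in LN (ratio 40100, 95% counting interval 7190 to 1580000), Rgs2 was 11.2-fold higher, and Itgae again had less in VAT without passing (15.8 ± 8.85 against 281 ± 67.0 CPM; adjusted p = 0.0925). Early response genes rose in 12 of 29 members (17 over the list alone; adjusted p = 8.59e-13), with Tnfaip3 16.2-fold and the AP-1 subunit gene Junb 3.89-fold higher. Checkpoint genes (2 of 18 rose, also over the list alone; adjusted p = 1.10e-08) and cytokine genes (3 of 17 rose; 10 rose and 1 fell over the list alone; 1.83e-07) were called as higher. Tnfrsf18 was 4.36-fold higher, and Xcl1, a ligand for cross-presenting dendritic cells, was 74.4-fold higher. Ifng (257 ± 11.5 against 1.72 ± 3.43 CPM), Tnf (166 ± 60.0 against 2.26 ± 4.50), Pdcd1 (144 ± 62.0 against 13.4 ± 19.6) and Gzmk (114 ± 19.1 against 3.26 ± 3.78) did not pass. Cish, a feedback inhibitor of cytokine signalling, had 221 ± 72.5 CPM in VAT and no count in LN (at least 4180-fold).

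The naive and central memory list had 11 of 22 that fell and 3 that rose (13 and 3 over the list alone; adjusted p = 2.34e-10), with Ly6c2 7.62-fold higher. Cd8a was 2.56-fold higher (1840 ± 145 against 718 ± 127 CPM) and Cd8b1 1.5-fold lower (1368 ± 280 against 2058 ± 99.7 CPM), although the call of Cd8b1 was lost without replicate 2 of lean LN (adjusted p = 0.0549) or replicate 2 of lean VAT (0.0512). The receptor complex list was not called (1 rose and 3 fell of 20; 3 and 6 over the list alone; adjusted p = 0.155). Cxcr3 was 5.05-fold and Cxcr6 3.38-fold higher, within a list of receptors and integrins that was not called (3 rose and 4 fell of 25; adjusted p = 0.583). Cd44 had 120 ± 90.6 against 21.2 ± 20.4 CPM and did not pass, nor did Cd3e (379 ± 25.8 against 364 ± 42.6 CPM). Heat shock genes rose in 3 of 17 members (5 over the list alone; adjusted p = 3.63e-05), Hspa8 2.80-fold, and apoptosis and p53 genes in 4 of 23 with 1 that fell (6 and 1 over the list alone; adjusted p = 0.00225), Gadd45g 10.6-fold. The oxidative phosphorylation list (1 of 52 rose; adjusted p = 0.00160), the unfolded protein response list (1 of 25 rose; 0.00598) and, in the lower direction, the mitochondrially encoded list (0 of 13 called; 0.0347) were called too. With an estimated correlation their adjusted p was 0.358, 0.177 and 0.513. Fatty acid genes were not called as a list (2 rose and 1 fell of 33; 0.787), but Dgat1 was 13.3-fold higher and Plin2, which coats lipid droplets, had 72.4 ± 38.3 CPM against 0.102 ± 0.0576. The cholesterol (adjusted p = 0.956), glycolysis (0.396), cell cycle (0.350) and type 17 (0.238) lists were not called.

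Markers of other cell types again moved with tissue. All 20 measured B and plasma cell genes were lower in lean VAT and 9 fell (17 over the list alone; adjusted p = 4.95e-19). Ighm was 12.4-fold lower (123 ± 49.4 against 1532 ± 265 CPM), and Fcmr had 79.2 ± 54.5 CPM in LN and no count in VAT. The fitted median was -10.09, or -8.74 with genes at 0 in a group set to their bound. The dendritic cell list was called as lower (3 of 14 fell; adjusted p = 0.0445, and 0.300 with an estimated correlation), with H2-Aa, an MHC class II chain, falling from 155 ± 94.0 CPM in LN to 4 counts in VAT. The natural killer list was called as higher (1 of 10 rose, 3 over the list alone; adjusted p = 2.20e-08), as was the CD4 and regulatory T cell list (3 of 8 rose; adjusted p = 0.00139). Il2ra, the IL-2 receptor alpha chain that activated CD8 cells also make, had 23.0 ± 15.3 CPM in VAT and no count in LN. The macrophage list was not called (3 of 8 rose; adjusted p = 0.114), and Plac8 was 11.8-fold and Lgals3 14.1-fold higher in it. The gamma delta list was not called (1 of 7 rose; adjusted p = 0.560). Among the small lists left untested, only the platelet gene Pf4 rose (17.8 ± 7.53 CPM against no count; adjusted p = 0.0437), and it lost the call without any single library of these groups (adjusted p up to 0.103). Pf4 is also a member of the macrophage list and is 1 of the 3 that rose there.

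Of the 476 genes called, 458 had no overlap between the groups, and over all genes tested the share without overlap was 12.9% where chance gives 2.86%. The count was 1569 with DESeq2, 1350 with limma voom and 195 with replicate numbers as blocks, and Gzmb lost its call with voom (adjusted p = 0.993) and with only these groups in the fit (0.0511). With blocks Cish, Gzmc, Ube2l6, Xcl1, Il2ra, Pf4, Fcmr and Cd8b1 lost their call (0.0941 to 0.362). Cish lost it also without the 3 VAT libraries of largest missing share (0.0539), Pf4 without a filter (0.0998), and Cd8b1 with upper quartile normalisation (0.0975), the stricter filter (0.0706) or only these groups in the fit (0.123). Gzmk, Ifng, Itgae, Pdcd1 and Tnf, which edgeR did not call, passed with voom (0.00137 to 0.0167), Itgae and Tnf passed with DESeq2, Itgae passed with only these groups in the fit (0.00558), Ifng passed without replicate 3 of lean LN (0.0141), and Tnf without replicate 1 of lean LN (0.0483). Left-out libraries ended list calls for oxidative phosphorylation (0.253 without replicate 1 of lean VAT), for mitochondrially encoded genes (up to 0.234, without replicates 2 or 4 of lean LN or 3 or 4 of lean VAT) and for the dendritic cell list (up to 0.154, without replicates 2 or 4 of lean LN or 1, 3 or 4 of lean VAT).

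**Figure D3:**
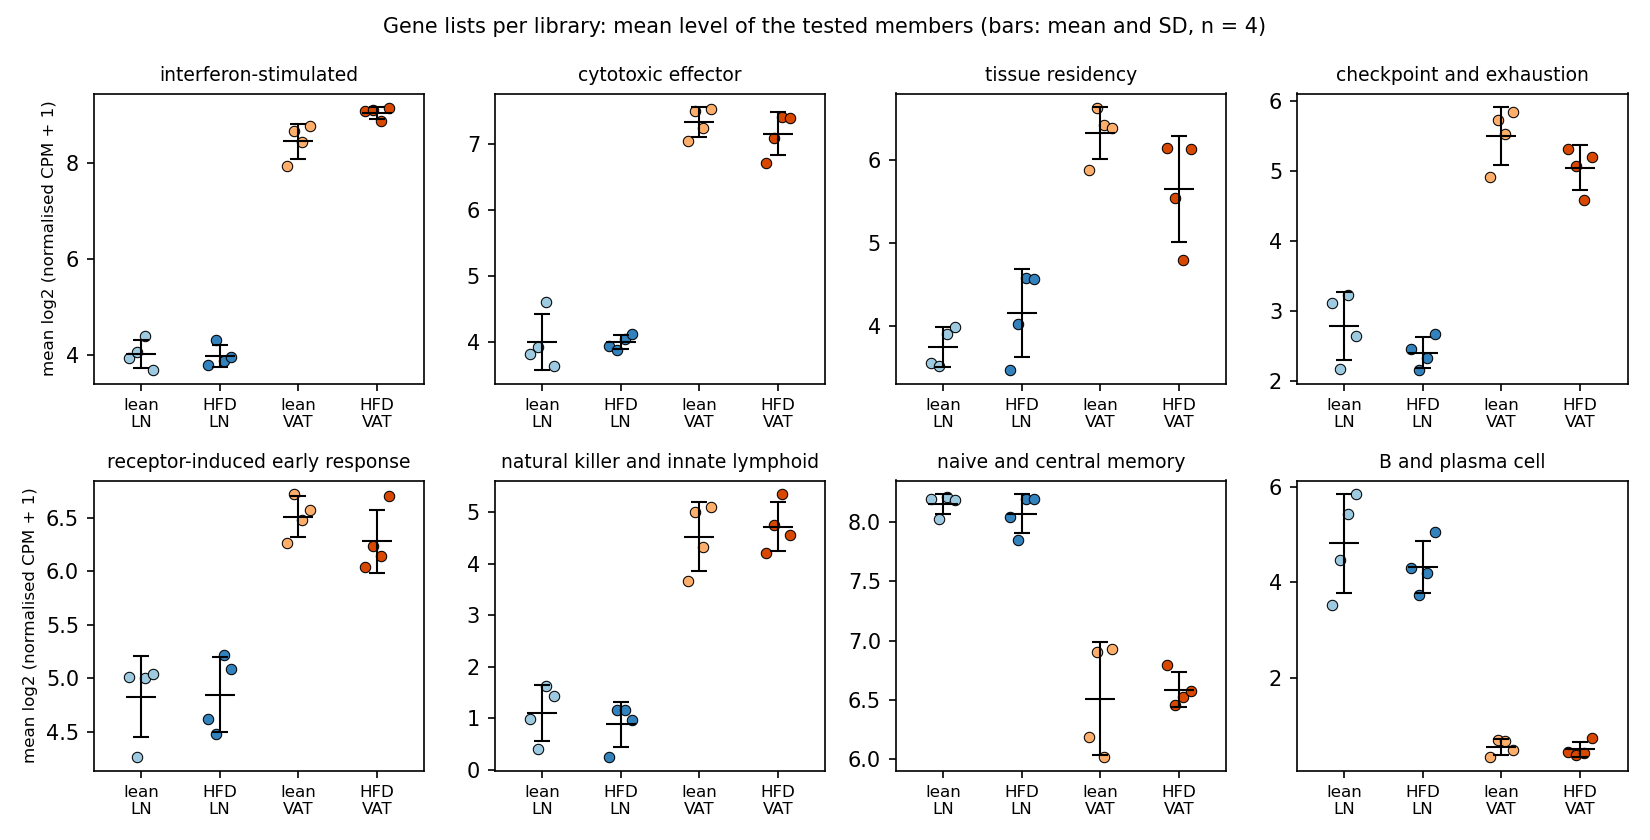
Mean log2 (normalised CPM + 1) over the tested members of 8 gene lists, with 1 point per library, the 4 groups along the horizontal axis and bars for mean and SD (n = 4). The interferon-stimulated list lies at 3.99 ± 0.231 in HFD LN, 4.02 ± 0.292 in lean LN, 8.45 ± 0.366 in lean VAT and 9.04 ± 0.125 in HFD VAT.

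The comparison of HFD with lean VAT asks what the diet changed in OT-I cells of fat. Interferon-stimulated genes were higher on HFD as a group: 34 of the 38 members lay above their lean level and 4 below, with a median log2 fold change of 0.45 and a mean of 0.49 (camera adjusted p = 1.00e-19). No member passed the gene test alone, over all genes or over the list. The members were shifted by far less than between the tissues. Irf7 was 3931 ± 275 CPM on HFD and 2722 ± 169 CPM in lean animals (adjusted p = 0.711). Usp18, which removes ISG15 from proteins and was chosen after its values were seen, was 1542 ± 192 against 786 ± 129 CPM (adjusted p = 0.629).

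The interferon call held with an estimated correlation (adjusted p = 0.00140), and fry, which asks only whether the members move 1 way on balance, gave an adjusted p of 0.000640. The mean log2 level of the list was 9.04 ± 0.125 on HFD and 8.45 ± 0.366 in lean VAT, with each HFD library above each lean library; the exact two-sided permutation p was 0.0286, the smallest that 4 against 4 allows, and 0.358 adjusted over 25 lists. Abundant genes in general lay slightly higher on HFD: 10000 random lists matched on level had a median log2 fold change of 0.13, with 0.38 the highest, and the interferon list lay above all of them. The receptor complex list was also called as higher (14 of 20 members higher, none called alone; adjusted p = 0.0140, and 0.0495 with an estimated correlation), but its median of 0.13 lay at percentile 45.8 of such random lists, and the call was lost without replicate 1 of HFD VAT (0.0628). The cholesterol synthesis list was called as lower (19 of 28 members lower, none called over all genes and 1 that fell over the list alone; adjusted p = 0.0313, and 0.279 with an estimated correlation). Its mean log2 level was 2.487 ± 0.426 on HFD and 3.417 ± 0.463 in lean VAT, again without overlap (exact p = 0.0286, adjusted 0.358), and fry gave an adjusted p of 0.0366. Its median of -0.48 lay at percentile 2.78, and the call was lost without replicates 1, 2 or 3 of HFD VAT or 4 of lean VAT (up to 0.162).

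Single genes called were few: 1 rose and 8 fell, with 1266 genes at an unadjusted p under 0.05. Cyb5r1, a reductase gene, had 39.7 ± 17.4 CPM in lean VAT and 1 count in HFD VAT (lean to HFD ratio 6760, 95% counting interval 1210 to 267000; adjusted p = 0.00240). Ndufaf2, an assembly factor of respiratory complex I, had 21.9 ± 23.1 CPM against 1 count (ratio 3720, interval 668 to 147000; adjusted p = 0.0128). Ddx11, a DNA helicase gene, had 54.4 ± 33.0 CPM against 1 count, and Slc49a4 had 28 ± 21.2 CPM against 2 counts. H2-Ob, a chain of the MHC class II modulator H2-O, had 13.4 ± 14.8 against 0.0964 ± 0.0473 CPM, and Klhl21 had 18.3 ± 13.9 against 0.0282 ± 0.0431. The named-gene rule does not take the other 3, which were named after their values were seen: Gabpb2 (28.5 ± 10.3 in lean VAT against 0.316 ± 0.411 CPM), the receptor segment Traj61 (1.91 ± 1.55 CPM against no count) and the pseudogene Selenot-ps, the gene that rose, which had no count in lean VAT and 0.385 ± 0.388 CPM on HFD and whose reads may belong to its parent gene. Cyb5r1 and Ndufaf2 kept their call without any single library (adjusted p up to 0.0108 and 0.0304), whereas Ddx11 (up to 0.181), H2-Ob (up to 0.123), Klhl21 (up to 0.119) and Slc49a4 (up to 0.115) each lost it without replicates 1 or 3 of HFD VAT or 2 or 4 of lean VAT. Ddx11 lost it also without replicates 2 or 4 of HFD VAT or 3 of lean VAT, H2-Ob without replicate 2 of HFD VAT, Klhl21 without replicate 3 of lean VAT, and Slc49a4 without either of these. With replicate numbers as blocks all 6 genes named by the rule lost their call (0.143 to 0.682). With only these groups in the fit Cyb5r1, Ndufaf2, Ddx11, H2-Ob and Klhl21 lost it (0.196 to 0.522), and with voom Cyb5r1, Ddx11, H2-Ob and Slc49a4 (0.0917 to 0.290). Ddx11, H2-Ob, Klhl21 and Slc49a4 lost it without a filter (0.0571 to 0.0871) or with the macrophage covariate (0.105 to 0.274), and Ddx11 without the 3 libraries of largest missing share (0.214). HFD VAT is the group with the fewest genes detected, and 2 of its libraries are among the 3 with the largest missing share.

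The T cell markers of the panel did not pass edgeR's test. Cd69 was 1115 ± 67.0 CPM on HFD and 636 ± 147 in lean VAT (adjusted p = 0.353), without overlap between the groups, Cxcr3 was 793 ± 144 against 598 ± 104 (0.618) and Gzmb was 10450 ± 3730 against 6896 ± 2470. Cd69 passed with DESeq2 and with voom (adjusted p = 0.00145 to 0.808 over 19 settings) and Gzmb with voom (0.000215 to 1 over 19 settings). Cd8a, Cd8b1, Cd3e, Cd44, Cxcr6, Gzmk, Ifng, Tnf, Itgae and Pdcd1 had adjusted p from 0.987 to 1. The effector and residency lists were not called (cytotoxic 0.0871, residency 0.972, checkpoint 0.900, cytokines 0.900, early response 0.486 with 2 members that rose over the list alone), nor were naive and central memory (0.0614), receptors and integrins (0.900), type 17 (0.692), cell cycle (0.900), fatty acid (0.795), glycolysis (0.0731), oxidative phosphorylation (0.0917), unfolded protein response (0.692), heat shock (0.987), apoptosis (0.730) or mitochondrially encoded genes (0.312). In 12 uncalled lists the mean log2 fold change was negative while the test pointed up: naive, cytotoxic, checkpoint, cytokine, receptor and integrin, early response, oxidative phosphorylation, unfolded protein response, apoptosis, B cell, macrophage and dendritic cell. Among lists of other cells the adjusted p was 0.900 for CD4 and regulatory T cells, 0.692 for gamma delta T cells, 0.227 for natural killer cells, 0.692 for B cells, 0.900 for macrophages and 0.900 for dendritic cells.

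All 9 genes had no overlap between the groups, and over all genes tested the share without overlap was 3.22% where chance gives 2.86%. In 6 of the 9 the lower group had 3 counts or fewer. The count depended strongly on settings: 769 with DESeq2, 62 without the 3 libraries of largest missing share, 32 with voom, 0 when only these groups were fitted, 40 without replicate 4 of HFD VAT, 23 without replicate 1 of lean VAT, and 4, 4 and 3 without replicates 2, 3 and 4 of lean VAT.

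**Figure D4:**
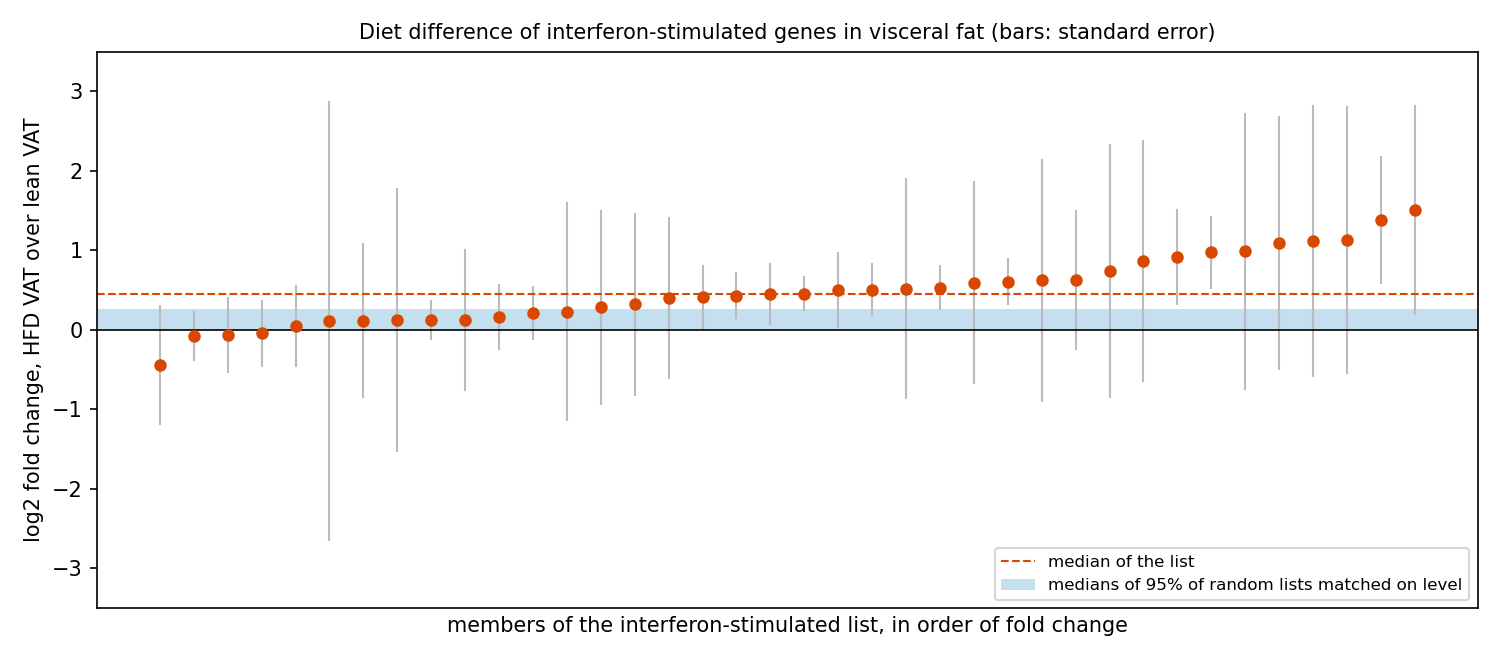
Log2 fold change, HFD VAT over lean VAT, of the 38 interferon-stimulated genes (points, with standard errors as bars), sorted by value, with the list median of 0.45 as a dashed line. The shaded band, 0.000552 to 0.264, holds the medians of 95% of 10000 random lists matched on level, and 34 of the 38 genes lie above 0.

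The comparison of HFD with lean LN asks what the diet changed in OT-I cells outside fat. No gene passed edgeR's test, with 529 at an unadjusted p under 0.05, and DESeq2 called 236 and voom 3. Without replicate 2 of HFD LN edgeR called 1. The interferon-stimulated list was not called (19 of 38 higher, 18 lower; adjusted p = 0.806), with Irf7 at 81.5 ± 36.0 CPM on HFD and 93.7 ± 28.8 in lean LN. Cxcr3 was 193 ± 44.7 CPM on HFD and 119 ± 13.3 in lean LN (1.63-fold; adjusted p = 1, and 0.0494 with DESeq2), Gzmb had 3 counts on HFD and 348 in lean LN, all in replicate 3 (adjusted p = 1, and 0.0356 with DESeq2), and Cxcr6 was 199 ± 39.3 against 262 ± 28.4. Cd8a (665 ± 112 against 718 ± 127), Cd8b1 (2072 ± 133 against 2058 ± 99.7) and Cd69 (108 ± 29.5 against 123 ± 32.8) differed by less than the spread between replicates.

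The gamma delta T cell list was called as higher on HFD (6 of 7 members higher, none called alone; adjusted p = 0.0276), with an adjusted p of 0.812 with an estimated correlation. The call was lost without replicates 2 or 3 of HFD LN or 1 or 2 of lean LN (up to 0.250). The other 24 lists were not called. The lowest adjusted p among them were 0.0719 for the type 17 list (10 of 13 higher), 0.0815 for residency (15 of 23 higher), 0.0815 for mitochondrially encoded genes (12 of 13 higher) and 0.0815 for B and plasma cells (15 of 20 lower). Genes whose groups did not overlap made up 2.26% of those tested, where chance gives 2.86%. In simulated data with the spread of these libraries, 20% of 65 genes changed 8-fold were called, so diet effects of that size in single genes can go undetected here. A shift of the interferon list by 0.5 (log2) in such data was not called either (adjusted p = 0.527). The same simulated shift between HFD and lean VAT was not called (0.0753), although the real list was, so the simulation does not match the sensitivity of the list test on the real libraries and does not say what size of list effect would be found in LN.

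The last comparison asks whether the diet effect differs between the tissues. In 3 genes it did: Cyb5r1 (log2 difference -12.28, adjusted p = 0.00878), Ndufaf2 (-11.34, 0.0476) and Traj61 (-9.75, 0.0461; outside the named-gene rule and named after its values were seen). Cyb5r1 had 73.7 ± 28 CPM in lean LN, 76.4 ± 55.0 in HFD LN, 39.7 ± 17.4 in lean VAT and 1 count in HFD VAT. Ndufaf2 had 17.7 ± 10.9, 17.2 ± 10.8 and 21.9 ± 23.1 CPM in the same 3 groups and 1 count in HFD VAT. Since HFD VAT is at or near 0 in each of them, these fitted differences depend on the prior count and give no size. Ndufaf2 lost its call without any single library except replicates 1, 2 or 4 of HFD VAT or 1 of lean VAT (adjusted p up to 0.279), and Cyb5r1 lost it without replicates 1, 2 or 3 of lean LN (up to 0.0687). Cyb5r1 lost it also with voom (0.325) and with replicate numbers as blocks (0.341), and Ndufaf2 with blocks (1), without a filter (0.179), with the stricter filter (0.0681), with upper quartile normalisation (0.0549) and with the macrophage covariate (0.0642).

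The interferon list did not pass this test (29 of 38 members with a larger HFD effect in VAT; adjusted p = 0.110), so its diet effect in VAT is not shown to differ from that in LN. None of the 25 lists passed in the main fit, the lowest adjusted p being 0.110, which mitochondrially encoded genes shared. The number of lists called was 3 without replicate 1 of lean VAT and 1 without replicate 3 of HFD VAT or replicates 1 or 2 of lean LN. Cd69, with 1115 ± 67.0 CPM in HFD VAT and 108 ± 29.5 in HFD LN, had a log2 difference of 0.99 between its diet effects (adjusted p = 0.544). Across genes the diet effects of VAT and LN had a Pearson correlation of 0.021. DESeq2 called 635 genes, and leaving out single libraries gave 0 (replicates 1, 2 or 3 of lean LN) to 24 (replicate 4 of HFD VAT), with 17 without replicate 1 of lean VAT, 2 without replicate 3 of HFD LN or 4 of lean LN, 12 without replicate 2 and 7 without replicate 1 of HFD VAT, and 1 without replicates 1 or 4 of HFD LN or 2, 3 or 4 of lean VAT. Where edgeR called 3 genes, 965 had an unadjusted p under 0.05.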

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

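The tests of splits and of the 3 libraries with the largest missing share, and the test of whether both tissues hold the same B cell transcripts, were chosen after the results were seen. The comparison of the interferon list with matched random lists, the count of absent genes over splits and the joint variation of B cell genes were written down before their results were seen. A sample was singled out when its gap to the nearest of the other 3 libraries of its group, over the group's range, exceeded Dixon's 95% critical value, which chance gives in about 1 of 20 groups. Of 180 such tests 19 did so, where 9 are expected.

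The interferon-stimulated list was higher in HFD VAT than in lean VAT, with a median log2 fold change of 0.45. Of the 35 splits of the 8 VAT libraries, 1, the real one, gave a camera p as small as 3.85e-18, and the smallest of the others was 8.02e-11. By the size of the shift, 2 of the 35 splits gave a mean log2 fold change as large as the real 0.489, the highest other being 0.502. The list was also singled out as the strongest of 25, so chance cannot be excluded. Without the 3 libraries with the largest missing share the camera adjusted p was 1.54e-22, although other splits also gave this list small p-values. The mean log2 level of the list in the libraries left was 9.09 and 9.14 on HFD and 8.42 to 8.76 in lean VAT. Those 3 libraries therefore do not account for the difference alone. The HFD VAT libraries left in that fit still missed more genes than the lean VAT libraries (4.18% and 5.31% against 0.797% to 1.65%). A general shift of abundant genes does not account for it either, since the list's median lay at percentile 100 of 10000 matched random lists. A hypothesis that stays open is that the diet raised interferon signalling in these cells, and unrecorded differences in the preparation of the groups may equally have done so. The difference between the diet effects of VAT and LN was not shown for this list (adjusted p = 0.110).

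Genes present in lean VAT and near 0 in all 4 HFD VAT libraries, such as Cyb5r1 and Ndufaf2, made up most of the single-gene differences by diet. The log2 difference between their diet effects in VAT and LN, by the test of that difference, was -12.28 for Cyb5r1, -11.34 for Ndufaf2 and -9.745 for Traj61. Of the 9 genes called, 7 kept their call without the 3 libraries with the largest missing share. Missing genes stay a possible cause, since the HFD VAT libraries left in that fit still missed more than the lean VAT libraries (4.18% and 5.31% against 0.797% to 1.65%). Random absence of genes from small samples is another. In all, 37 genes were at 3 counts or fewer in every HFD VAT library with a median of at least 10 CPM in lean VAT. As many were found in 5 of the 35 splits, up to 69. Each such split other than the real one set 3 HFD VAT libraries with replicate 1 of lean VAT, whose missing share was 13.1%. These splits keep most of the diet grouping, so they cannot tell random absence from a structure of the libraries or from an effect of diet. Chance cannot be excluded for the count of genes either, since 4 of 35 splits called 9 or more, and the 38 genes of the highest split, which sets replicates 1, 2 and 3 of HFD VAT with replicate 1 of lean VAT against the rest, point to a structure of the libraries.

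B cell transcripts were abundant in LN libraries (summed 2461 ± 343 CPM on HFD and 2781 ± 937 CPM in lean animals) and low in VAT (240 ± 88.1 and 132 ± 54.8 CPM), although the labels describe a sort for T cells. B cells or their RNA among the LN cells are a candidate source. The 20 B and plasma cell genes varied together over the 8 LN libraries, with a mean pairwise correlation of 0.335. The highest of 2000 matched random lists had 0.171 (percentile 100). These lists were matched on level only, so the test cannot tell B cells from another source of variation that such genes share. The summed levels argue against a source shared alike by both tissues. Of 9 members found in every LN library, 1 was above 3 counts in at least 4 VAT libraries. These members were picked by their LN counts after the tissue difference was seen, so that count adds no separate support. Ighm (1527 ± 245 CPM in HFD LN) was among the abundant genes of the B and plasma cell list. Cd74 (365 ± 151 CPM), which B cells share, belongs to the dendritic cell list and is not part of these sums. Whether the differences of other LN genes carry a part from such cells was not tested.

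Total counts were 65957407 in replicate 1 of lean LN, against 49323455 to 51262806 in the others of its group. In replicate 1 of lean VAT the mitochondrially encoded share was 0.339% against 0.132% to 0.156%, the missing share was 13.1% against 0.797% to 1.65%, and the mean log2 level was 5.06 for heat shock genes against 6.30 to 6.34 and 5.81 for mitochondrially encoded genes against 5.07 to 5.11. In replicate 2 of lean LN the missing share was 5.19% against 1.48% to 1.99%, and the mean log2 level was 8.03 for naive and central memory genes against 8.19 to 8.21 and 4.26 for early response genes against 5 to 5.04. In replicate 2 of lean VAT the mean log2 level was 8.89 (8.885) for the receptor complex list against 8.83 to 8.84 and 6.29 for cytokine genes against 5.87 to 5.92. In replicate 4 of lean LN the CD4 and regulatory T cell list was at 2.61 against 1.62 to 1.76.

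Of single genes, on the scale of log2 (CPM + 1), Itgae was 7.51 (7.515) in replicate 2 of lean LN against 8.23 to 8.33, and Cxcr6 9.85 in replicate 1 of HFD VAT against 9.64 to 9.66. Replicate 3 of lean LN held Gzmb at 2.95 and Ifng at 2.98 against 0 in the others. Tnf was 3.33 (3.328) in replicate 4 of HFD LN and 3.33 (3.325) in replicate 1 of lean LN against 0.0314 or less in the others of their groups, and 3.53 in replicate 1 of HFD VAT against 6.75 to 7.32. Pdcd1 was 1.13 in replicate 3 of HFD LN against 0.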

How the results depend on the processing

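The fits without 3 VAT libraries, with genes of at least 50 CPM and with held voom weights were chosen after seeing the data. No called list and no called gene named by the rule changed direction in any setting where it was fitted. Other called genes were not followed one by one. For HFD against lean VAT the gene count of 9 became 2 without a filter, 769 with DESeq2, 32 with voom, 0 with only the groups compared, 0 with replicate blocks, 3 with the macrophage covariate, 62 without the 3 libraries, 3 at 50 CPM or more, and 3 to 40 when single libraries were left out. Its list count of 3 became 7 with RLE, 2 with an estimated correlation and 1 to 4 with libraries left out. The interferon list kept its call in all 12 settings run (adjusted p 1.54e-22 to 0.00140). For HFD against lean LN the gene count of 0 became 236 with DESeq2, 3 with voom, 1 with blocks and 0 to 1 with libraries left out, and the list count of 1 became 0 with an estimated correlation, 4 with blocks and 0 to 2. For tissue on HFD the gene count of 714 became 441 without a filter, 2578 with DESeq2, 264 with blocks and 483 to 632 with libraries left out, and the list count of 16 became 10 with an estimated correlation and 15 to 17. For tissue in lean animals 476 became 1569 with DESeq2, 1350 with voom, 195 with blocks and 325 to 492, and 16 lists became 12 with an estimated correlation, 17 with held weights and 14 to 16 with libraries left out. For the difference between diet effects 3 genes became 1 with upper quartile, without a filter, with the stricter filter or with the macrophage covariate, 635 with DESeq2, 6 with voom, 0 with blocks, 46 without the 3 libraries, 0 at 50 CPM or more and 0 to 24 with libraries left out. Its 0 lists became 1 with blocks, with RLE or with held weights (with held weights the interferon list), 2 without the 3 libraries and 0 to 3. In simulated data DESeq2 called 149 to 212 unchanged genes and edgeR 0. Otherwise the cause was not tested. RLE moved the median log2 difference between diet effects over all genes from -0.11 to -0.01. List tests without replicate 2 of lean VAT could not be fitted, because voom gave the most abundant genes weights without bound. Such weights were also present in the voom fit of all 16 libraries behind the main list tests. There the largest was 5.98e+09 and the 99th percentile 28.2, with 344 genes above it. Whether such weights lie behind the voom results of abundant genes such as Gzmb was not tested. The replicate numbers carried no sign of animals shared between tissues: residual correlations of same-numbered libraries were -0.098 to 0.033, and the own partner was the best in 1 of 8. Between diets these values were -0.027 to 0.045 and 3 of 8. Animals of different diets are different animals, so the latter say nothing on shared animals, and blocks in the diet comparisons pair animals by number only. Genes at 3 counts or fewer in a group limit every fold given against it.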

Other observations

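Genes named here were chosen after their values were seen, as was every test below. Single genes outside the lists were higher in VAT on both diets, some of them with a part in antigen presentation by MHC class I, for which no list was tested. B2m, H2-T23, Tapbp, Psmb10 and Igtp each passed edgeR's test on both (adjusted p up to 0.00316, for Tapbp in lean animals). B2m, the light chain shared by class I molecules, was 8140 ± 306 against 2931 ± 206 CPM on HFD and 7354 ± 1472 against 2791 ± 536 CPM in lean animals. H2-T23, a non-classical class I gene, was 2544 ± 181 against 610 ± 18.4 CPM on HFD and 1981 ± 35.4 against 669 ± 88.5 CPM in lean animals, though class I genes share sequence and reads may be divided between them. Tapbp, which loads class I molecules, was 1602 ± 337 against 528 ± 103 CPM on HFD, and Psmb10, an immunoproteasome subunit gene, 673 ± 189 against 181 ± 14.6 CPM. Igtp, an interferon-inducible GTPase outside the interferon list, was 1183 ± 242 against 91.9 ± 34.5 CPM on HFD and 770 ± 155 against 123 ± 41.1 CPM in lean animals.

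Il2rb, Ifngr1, Stat3, Odc1 and Ccnd2 were also higher in VAT and passed the same test on both diets (adjusted p up to 0.000139, for Il2rb on HFD). Il2rb, the receptor chain shared by IL-2 and IL-15, was 1088 ± 268 against 307 ± 55.7 CPM on HFD and 1216 ± 139 against 240 ± 56.2 CPM in lean animals. Ifngr1 was 3322 ± 228 against 839 ± 95.7 CPM and 2984 ± 1056 against 687 ± 101 CPM, and Stat3 was 1045 ± 218 against 238 ± 33.0 CPM and 850 ± 89.1 against 246 ± 54.5 CPM. Odc1, the first enzyme of polyamine synthesis, was 716 ± 139 against 29.7 ± 5.99 CPM on HFD and 498 ± 155 against 27.0 ± 9.87 CPM in lean animals. Ccnd2, a G1 cyclin gene, was 964 ± 115 against 128 ± 39.1 CPM on HFD, while the cell cycle list was not called.

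The ratio of Cd8a to Cd8b1 was 1.71 ± 0.268 in HFD VAT, 1.40 ± 0.339 in lean VAT, 0.320 ± 0.0354 in HFD LN and 0.348 ± 0.0546 in lean LN. On both diets every VAT library lay above every LN library (exact two-sided permutation p = 0.0286, the smallest possible), which did not pass the threshold after adjustment over the 4 comparisons (adjusted p = 0.0572). For diet the exact p was 0.257 in VAT (adjusted 0.343) and 0.429 in LN (adjusted 0.429). No explanation of the ratio was tested.

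Splits of the same libraries set the other counts in proportion. For tissue on HFD 1 of 35 splits, the real one, gave as many as 714 genes, the highest other giving 2. For tissue in lean animals 1 of 35 gave 476, the highest other giving 1. No other split came near the real count, though 1 of 35 is the smallest share this test can give, and the other splits mix the tissues. With held weights the real split called 17 lists on HFD and 17 in lean animals, with 15 and 16 in the highest other, each reached in 1 of 35. In VAT by diet 1 of 35 splits called as many as 4 lists, the highest other calling 3. In LN by diet the real split called 0 genes and the others up to 3, so the splits cannot test that count. Chance cannot be excluded for the lists there, where 28 of 35 splits called 1 or more (up to 6). It cannot be excluded for the difference between diet effects either, where 26 of 100 splits called 3 or more genes (up to 28) and 57 of 100 called 1 or more lists (up to 6).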
